A study of Rattus norvegicus with 19 samples.

How the data were processed

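RNA sequencing of sorted mast cells from newborn rats was analysed in 19 libraries. Per the labels, wild-type pups were perfused with saline at postnatal day 2 (PN2) or 7 (PN7), immune cells were enriched on a Percoll gradient, and live single cells with high CD45, no CD11b and surface FcεRI were sorted. The labels describe the replicates as independent, each holding cells pooled from 6 animals. Animals within a pool cannot be separated, so the p-values measure the spread between pools. Per the labels' protocols, cDNA was made with a SMART-Seq v4 low-input kit and libraries with Nextera XT, and both amplify by PCR without molecular identifiers; counting intervals and floors given below therefore cover counting error only.

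The authors deposited a table of estimated counts per transcript, and the values are not normalized between libraries. Per the submitters' processing notes, kallisto and the rat genome build Rnor_6.0 were used; the version and settings are not given in the sources used here. kallisto divides reads that fit several transcripts among them. Of the 29107 transcripts, 4511 had a value of 0 in all libraries, and 3688 others held values identical in all 19 libraries to at least 1 other transcript. Among transcripts with any reads, 72.4% of the values were whole numbers within a tolerance of 1e-06. Column totals ran from 5495252 to 26394623 per library.

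Rows carry Ensembl transcript identifiers, and the files do not pair them with gene names. The gene table used here, for a later assembly, lists 47357 genes and holds an Ensembl identifier for 0 of them, so 0 transcripts could be named. The 44 gene lists with 769 genes written before the data were examined could not be matched, and their tests (camera, and fry as the alternative) were not run. All results are at the level of transcripts: a shift between isoforms of a gene cannot be told from a change in the gene's total, and reads shared by near-identical transcripts were split by the authors' counting.

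Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3. Transcripts were kept by filterByExpr over the 6 groups, which left 20521, of which 2245 had values identical to another kept transcript. Library sizes were scaled by TMM. All 19 libraries entered 1 quasi-likelihood fit of group means (glmQLFit, robust), so that groups share an estimate of the spread, and each comparison was tested with glmQLFTest. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test, with calls made below 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, that is counts relative to the library's scaled total. Correlations and principal components used log2 CPM with a prior count of 2. Class sums were compared with exact permutation tests in SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. The deposited unit and the main test were as foreseen; the level was transcripts where genes had been planned.

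The rule for named transcripts took the largest fitted rises and falls of 5 comparisons with an adjusted p below 0.05, a mean of at least 10 CPM in the higher group and no overlap between libraries. Without gene names, the rule's condition on symbols could not be applied, and its parts on listed genes and cell-identity genes were dropped. Only 2 identifiers per direction and comparison are printed. A fold against a group with 0 counts is a lower bound computed against a floor of 3 counts over the whole group.

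The comparisons, tests, named-transcript rule and the first set of alternatives were fixed before the data were examined. These alternatives were DESeq2 size factors (RLE) in the same edgeR fit, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, no low-count filter, a stricter filter (5 CPM in at least 3 libraries), only the libraries of the groups compared, the replicate number as a block, and each replicate left out in turn. Added after seeing the data were merging identical transcripts, leaving out the libraries numbered 4 and 5, a term for those libraries, thinning every library to the smallest total, and other fold limits for the restricted classes. The classes themselves, transcripts of at least 100 CPM in bone marrow or skin and at least 50-fold above the other of both tissues, were also defined after seeing the data.

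The test was tried on simulated counts with 50 transcripts changed at each fold. All libraries were drawn from the same means with 1 shared dispersion per transcript, and only transcripts of at least 5 CPM were changed. The real hypothalamus libraries of PN2 correlated at 0.821, against means of 0.926 to 0.954 within the other groups with replicates. The simulated recovery and false calls may therefore not hold for comparisons with hypothalamus. With 20519 transcripts in the hippocampus against bone marrow setting, 40% of the 2-fold and 82% of the 4-fold changes were recovered, with 8 false calls. With 20513 transcripts in the setting of hippocampus PN7 against PN2, 36% and 74% were recovered, with 2 false calls. With 20515 transcripts in the setting of hypothalamus against hippocampus PN2, 34% and 72% were recovered, with 5 false calls. With 20517 transcripts in the setting of hypothalamus PN7 against PN2, which has 1 library against 2, 8% and 52% were recovered, with 1 false call.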

Results

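Mast cells, tissue immune cells that carry the high-affinity IgE receptor FcεRI, were sorted from 4 rat tissues in the first postnatal week. Their RNA was sequenced in bulk. Without gene names no marker could be read, so the purity of the sorts was not checked in any tissue. Below, mast cells means the sorted cells, and a share of other cells in them was not tested. At PN2 there were 4 libraries from bone marrow, 5 from skin, 4 from hippocampus and 2 from hypothalamus. At PN7 there were 3 from hippocampus and 1 from hypothalamus, and this lone library has no replicates. Total estimated counts ran from 16196856 to 22563833 in bone marrow, from 11704985 to 26394623 in skin and from 19935250 to 22967152 in hippocampus at PN2. The hippocampus libraries of PN7 held 10329777 to 12870442, and the 2 hypothalamus libraries of PN2 held 5495252 and 5607810. The hypothalamus library of PN7 held 9792422.

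Bone marrow mast cells stood apart from those of the other 3 tissues. The first principal component, with 28.2% of the variance, separated bone marrow from the rest, and the second, with 13.4%, ran from skin through hippocampus PN2 and hippocampus PN7 to hypothalamus. Across transcripts, log2 CPM of hippocampus PN2 and skin libraries correlated at a mean r of 0.915 over 20 pairs, against 0.842 for hippocampus PN2 and bone marrow over 16 pairs. Replicates within a group correlated at 0.947 in bone marrow, 0.954 in hippocampus PN2, 0.945 in skin and 0.926 in hippocampus PN7, whereas the 2 hypothalamus libraries of PN2 correlated at 0.821. These correlations are across transcripts, which are not independent replicates. In a check for a library deposited more than once, no pair of replicates came near counting noise. The lowest chi-square per degree of freedom was 15.2, for skin replicates 4 and 5. These 2 also lay close together on the first component (41.1 and 41.8) and the second (-111 and -112). PCR amplification could lift libraries from the same pool above counting noise too. The check therefore cannot tell such libraries from separate pools, and the 5 skin libraries are counted as separate on the labels' word.

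**Figure D1:**
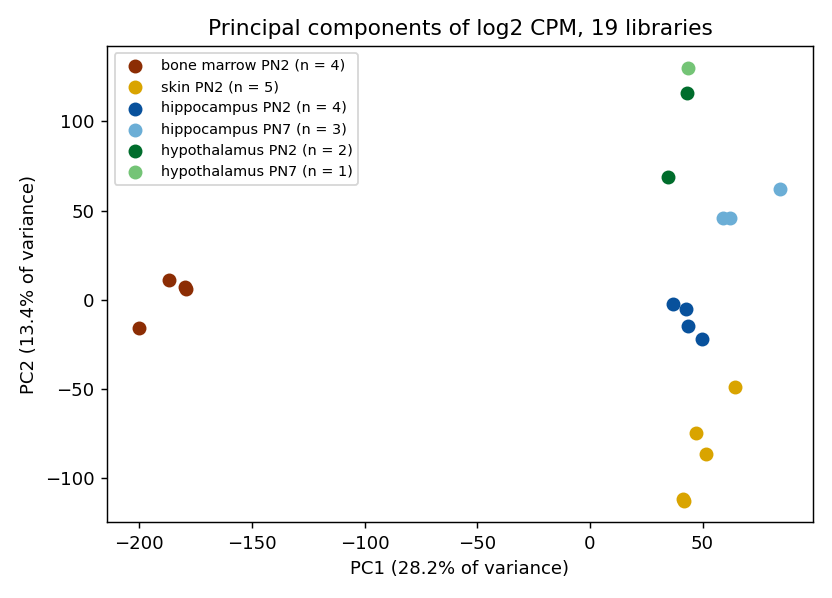
Each point is a library placed by its scores on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by tissue and age. The 4 bone marrow libraries lie on the left, and the other 15 on the right spread along the second component from skin to hypothalamus.

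Hippocampal mast cells at PN2 differed from bone marrow mast cells in 5897 of 20521 transcripts, 3251 higher and 2646 lower in hippocampus. Changes were large: 1642 of the higher and 1227 of the lower transcripts differed by at least 4-fold, and 437 of the higher transcripts had 0 counts in every bone marrow library. Transcript ENSRNOT00000010645.7 averaged 308 ± 38.1 CPM in hippocampus (SD, n = 4) and had 1 count over the 4 bone marrow libraries, a ratio of 26583 with a 95% counting interval from 4888 to 1075700. ENSRNOT00000022113.4 averaged 3202 ± 2274 CPM in hippocampus (SD, n = 4) and 0.0717 ± 0.0874 CPM in bone marrow (SD, n = 4), a log2 fold change of 15.19 ± 1.65 (SE; adjusted p = 2.92e-06, edgeR). In the other direction, ENSRNOT00000018767.3 averaged 189 ± 98.7 CPM in bone marrow (SD, n = 4), had 0 counts in hippocampus and was thus at least 5167-fold lower there. ENSRNOT00000012494.6 averaged 877 ± 1455 CPM in bone marrow (SD, n = 4), where replicate 4 held 3057 CPM and the other 3 averaged 151 CPM, and had 1 count over the hippocampus libraries. With limma voom the number called was 9533. Without the libraries numbered 4 and 5, which deviated together across tissues, 5008 transcripts were called.

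Skin and bone marrow mast cells at PN2, both from outside the brain, gave the scale for this difference. They differed in 6981 transcripts, 3521 higher and 3460 lower in skin. ENSRNOT00000075775.2 averaged 140 ± 31.0 CPM in skin (SD, n = 5) with 0 counts in bone marrow, at least 4131-fold higher in skin. ENSRNOT00000049667.3, whose values are identical to those of another transcript in all libraries, averaged 2525 ± 374 CPM in skin (SD, n = 5) against 0.240 ± 0.192 CPM in bone marrow (SD, n = 4), a log2 fold change of 13.24 ± 0.85 (SE; adjusted p = 5.08e-09, edgeR). ENSRNOT00000035128.4 averaged 1009 ± 818 CPM and ENSRNOT00000056845.4 averaged 479 ± 252 CPM in bone marrow (SD, n = 4 each), and both had 0 counts in skin, at least 36451-fold and 17313-fold lower. Bone marrow replicate 4 held 2115 CPM of ENSRNOT00000035128.4, and without it the bound is 23142-fold. Without the libraries numbered 4 and 5, 5923 transcripts were called.

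Mast cells of hippocampus and skin differed from bone marrow in overlapping sets of transcripts. Of the transcripts higher in hippocampus and those higher in skin than in bone marrow, 2398 were in both sets, against 558 for independent lists. Of the lower ones 2111 were in both, against 446. Both comparisons use the same bone marrow libraries. Simulated unchanged groups against these libraries made 0 calls in either list, so no overlap of calls could arise there. With the bone marrow libraries divided between both tests, 1603 higher and 1461 lower transcripts were shared, against 280 and 263 for independent lists. The covariance of the log2 fold changes was 5.08 with the bone marrow libraries shared and 4.43 with them divided. For the simulated unchanged groups it was 0.0720. These groups were drawn around the mean of the same bone marrow libraries, which leaves out the error of that mean. Their value therefore does not measure what sharing the libraries adds.

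**Figure D2:**
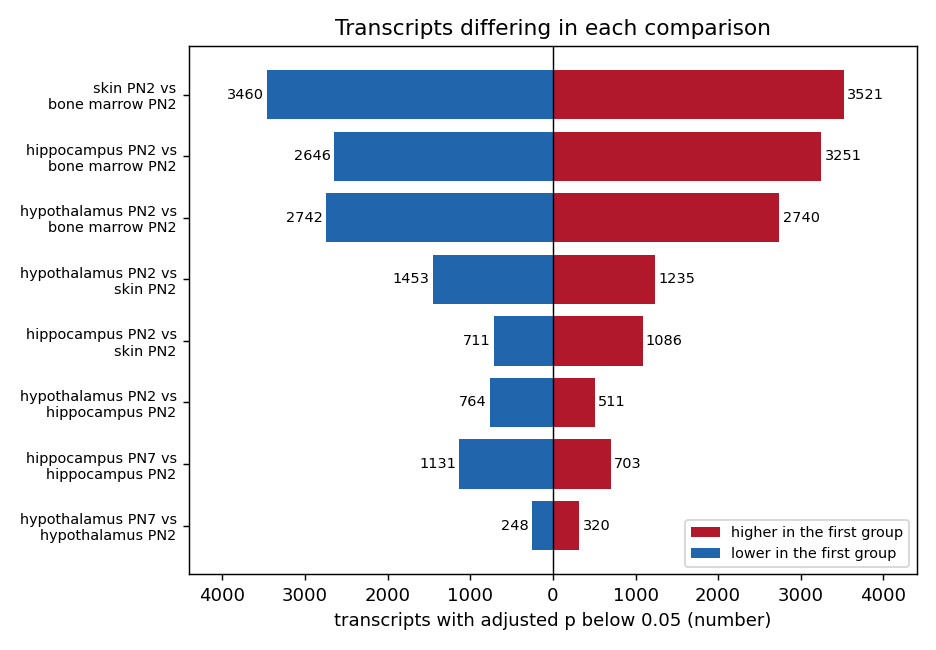
Bars give the number of transcripts with an adjusted p below 0.05 in each comparison (x axis, number of transcripts, counted outward from 0 in both directions), higher to the right and lower to the left in the first group named. Counts run from 6981 for skin against bone marrow to 568 for hypothalamus PN7 against PN2, which rests on 1 library at PN7.

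Hippocampal mast cells at PN2 differed from skin mast cells in 1797 transcripts, 1086 higher and 711 lower in hippocampus. ENSRNOT00000022113.4, also among the largest rises against bone marrow, averaged 0.164 ± 0.264 CPM in skin (SD, n = 5), a log2 fold change of 14.10 ± 1.41 (SE; adjusted p = 1.05e-05, edgeR). ENSRNOT00000051139.5 averaged 51.6 ± 35.0 CPM in hippocampus (SD, n = 4) with 0 counts in skin, at least 1862-fold higher. Over hippocampus replicates 1 to 4 it held 78.7, 29.5, 14.1 and 83.9 CPM. ENSRNOT00000022113.4 held 3925, 1412, 1368 and 6104 CPM in the same order, so these 2 rises may not be independent. ENSRNOT00000005285.4 and ENSRNOT00000011644.5 averaged 17.7 ± 15.2 and 13.3 ± 7.61 CPM in skin (SD, n = 5 each) with 0 counts in hippocampus, at least 484-fold and 365-fold lower. Skin replicates 4 and 5 held 33.8 and 34.3 CPM of ENSRNOT00000005285.4, against 2.16 to 9.55 CPM in the other skin libraries. Of ENSRNOT00000011644.5 they held 19.7 and 22.75 CPM, against 4.595 to 10.8 CPM, so both bounds rest largely on these libraries. Relative to both tissues, 457 transcripts were higher in hippocampus than in bone marrow and in skin alike, and 187 were lower than in both. Independent lists would give 172 and 91.7. A further 385 lay between bone marrow and skin, and no value for independent lists was computed for them. Both lists use the same hippocampus libraries; with these divided between both tests in either way, 215 and 216 were higher and 56 and 54 lower, against at most 67.3 and 19.2 for independent lists. The 457 became 1253 with limma voom, and the 187 became 106 and 111 without hippocampus replicate 2 or 3, 447 with DESeq2 and 555 with limma voom. The count of 1797 fell to 1183 without hippocampus replicate 2 and 1189 without hippocampus replicate 3, and was 2819 with DESeq2, 4653 with limma voom and 2796 with only the groups compared. Without the libraries numbered 4 and 5 it was 1343.

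Transcripts that tell bone marrow from skin showed where the brain mast cells lay between both. The 83 bone-marrow-restricted transcripts summed to 168700 CPM in bone marrow and 160 CPM in skin. They summed to 5430 ± 979 CPM in hippocampus at PN2 (SD, n = 4), 3.22% of the bone marrow level, and to 6722 ± 1626 CPM at PN7 (SD, n = 3), 3.98% of it. In hypothalamus they summed to 19403 ± 610 CPM at PN2 (SD, n = 2), 11.5% of the bone marrow level, and to 55381 CPM in the PN7 library, 32.8% of it. The median transcript of the class lay at 1.05% and 1.10% of its bone marrow level in these groups, and 5 of the 83 transcripts held 82.1% and 78.7% of the class's reads. With the fold limit for the class raised to 200, chosen after seeing the data, these shares were 0.378%, 1.42%, 4.97% and 15.1%, in the same order, and 3.66%, 4.72%, 11.6% and 32.3% at 20. The 38 skin-restricted transcripts summed to 81119 ± 12924 CPM in skin (SD, n = 5) and 69836 ± 2945 CPM in hippocampus at PN2 (SD, n = 4), 86.1% of the skin level. They summed to 81451 ± 3824 CPM in hippocampus at PN7 (SD, n = 3) and 40778 ± 7847 CPM in hypothalamus at PN2 (SD, n = 2), 100.4% and 50.3% of the skin level, and to 27350 CPM in the hypothalamus library of PN7, 33.7% of it. With the fold limit at 200, which leaves 13 transcripts and was also chosen after seeing the data, the shares were 45.8% in hippocampus at PN2, 71.4% at PN7, 41.0% in hypothalamus at PN2 and 36.8% in its PN7 library. At 20, with 81 transcripts, they were 90.8%, 86.2%, 54.5% and 31.5%, so the order of hippocampus at PN2 and PN7 was reversed. Among 5 exact two-sided permutation tests of these sums, hypothalamus against hippocampus at PN2 gave p = 0.133 for both classes, the smallest that 2 against 4 libraries allow. Hippocampus PN7 against PN2 gave p = 0.286 for the bone marrow class and, in the same exact tests, p = 0.0571 for the skin class, the smallest that 3 against 4 libraries allow. Hippocampus against skin at PN2 gave an exact p = 0.159, and all adjusted values were at least 0.198. The skin class was picked for its level in these same skin libraries, which favours a higher sum in skin in this last test and in the shares above.

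**Figure D3:**
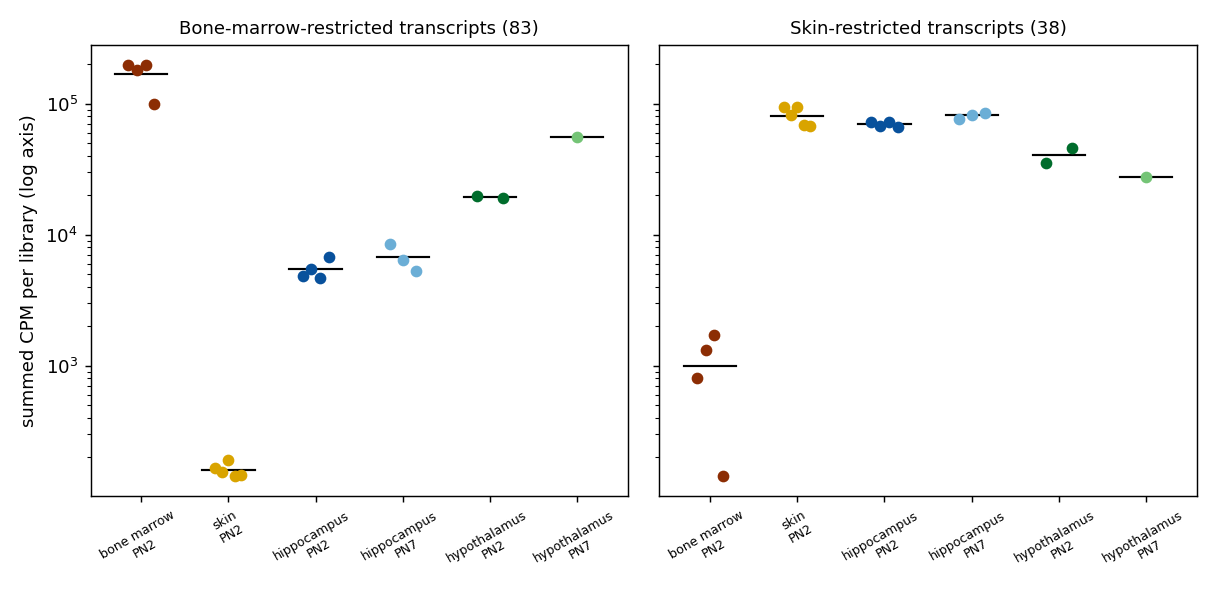
Each point is a library, black lines are group means, and the y axis is the summed CPM of the class on a log axis, for 83 bone-marrow-restricted transcripts (left) and 38 skin-restricted transcripts (right) over 6 groups (x axis). Bone-marrow-restricted transcripts summed to 160 CPM in skin, 5430 CPM in hippocampus PN2 and 19403 CPM in hypothalamus PN2; both classes were picked on their bone marrow and skin levels.

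Hypothalamic mast cells at PN2 differed from hippocampal ones in 1275 transcripts, 511 higher and 764 lower in hypothalamus. The balance of directions changed with the fit: it was 623 higher and 570 lower with RLE factors, 251 and 20 with limma voom, 152 and 81 with only the groups compared and 666 and 663 with the stricter filter. The 2 hypothalamus libraries differed in complexity: 16231 transcripts had any count in replicate 1 and 13403 in replicate 2, and the top transcript took 6.90% and 16.6% of the counts. Without replicate 1, 951 transcripts were higher and 2448 lower, with a median log2 fold change of -0.50 over all transcripts against -0.14; without replicate 2, 656 were higher and 928 lower. ENSRNOT00000023506.6 averaged 24.8 ± 31.5 CPM in hypothalamus (SD, n = 2) with 0 counts in hippocampus at PN2, at least 678-fold higher. Its hypothalamus libraries held 47.0 and 2.49 CPM, and without replicate 1 the bound is 68.0-fold, without replicate 2 1287-fold. ENSRNOT00000083045.1 averaged 19.5 ± 3.48 CPM in hypothalamus (SD, n = 2) and had 2 counts over the hippocampus libraries, a ratio of 757 with a 95% counting interval from 222 to 6611. ENSRNOT00000010325.5 and ENSRNOT00000051139.5 averaged 59.1 ± 35.3 and 51.6 ± 35.0 CPM in hippocampus (SD, n = 4 each) with 0 counts in hypothalamus at PN2, at least 215-fold and 188-fold lower. These 2 also varied together over hippocampus replicates 1 to 4, at 87.0, 34.9, 22.7 and 91.7 CPM and 78.7, 29.5, 14.1 and 83.9 CPM. The call on ENSRNOT00000083045.1 (adjusted p = 0.0377, edgeR) was lost without any of the hippocampus replicates, without hypothalamus replicate 2 and with the replicate block. Those on ENSRNOT00000023506.6 and ENSRNOT00000051139.5 were lost with only the groups compared, and those on ENSRNOT00000010325.5 and ENSRNOT00000051139.5 with limma voom. The number of calls changed with the fit: with only the libraries of both groups it was 233, with limma voom 271 and with DESeq2 2365. It was 817, 845 and 796 without hippocampus replicate 1, 2 or 3, 3399 without hypothalamus replicate 1, and 2124 without the libraries numbered 4 and 5.

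Against the tissues outside the brain, hypothalamic mast cells at PN2 differed from bone marrow in 5482 transcripts, 2740 higher and 2742 lower, and from skin in 2688, 1235 higher and 1453 lower. The balance of directions changed with the fit and the libraries. Against bone marrow it was 1361 higher and 917 lower with limma voom, and 2397 and 3732 without hypothalamus replicate 1. Against skin it was 1397 higher and 1294 lower with RLE factors, 460 and 138 with limma voom, 1285 and 1222 with the stricter filter, and 1382 and 2694 without hypothalamus replicate 1. Of the transcripts higher than in skin, 443 were shared between hypothalamus and hippocampus, against 65.4 for independent lists, and of the lower ones 355, against 50.3. Simulated unchanged groups against the same skin libraries made 0 calls, so no overlap could arise there. The covariance of the log2 fold changes was 2.26, and 0.213 for these simulated groups. They were drawn around the mean of the shared skin libraries, so 0.213 does not measure what sharing adds. With the skin libraries divided between both tests, 222 and 190 were shared, against 14.9 and 15.9 for independent lists. The covariance was then 1.40. With only the groups compared, 1962 and 1451 transcripts were called against bone marrow and skin, with limma voom 2278 and 598, and 4076 were called against skin without hypothalamus replicate 1.

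Hippocampal mast cells of PN7 differed from those of PN2 in 1834 transcripts, 703 higher and 1131 lower at PN7. The called changes were smaller in size than those between tissues at PN2. Of the higher transcripts 113, and of the lower 219, differed by at least 4-fold. The median size of a called log2 fold change was 1.06, against 1.92 for hippocampus against bone marrow. It was 1.37 for hippocampus against skin and 1.57 for hypothalamus against hippocampus at PN2. Those last 2 comparisons did not call more transcripts than the 1834, with 1797 and 1275. ENSRNOT00000042459.4 and ENSRNOT00000042553.3 averaged 241 ± 201 and 60.9 ± 27.5 CPM at PN7 (SD, n = 3 each) with 0 counts at PN2, at least 6600-fold and 1666-fold higher; without PN7 replicate 2 the first bound is 4027-fold. The call on ENSRNOT00000042459.4 (adjusted p = 0.0389, edgeR) was lost in every fit without 1 of the 7 libraries, with adjusted p from edgeR between 0.0521 and 0.0903, without a low-count filter, with the replicate block and in both fits that set the libraries numbered 4 and 5 apart. That on ENSRNOT00000042553.3 was lost without any of the 4 PN2 libraries. ENSRNOT00000020049.4 and ENSRNOT00000086716.1 averaged 27.8 ± 4.23 and 11.0 ± 4.70 CPM at PN2 (SD, n = 4 each) with 0 counts at PN7, at least 307-fold and 122-fold lower. Age goes with depth here, since every PN7 library held fewer counts (at most 12870442) than every PN2 library (at least 19935250). With every library thinned to the smallest total, 1763 transcripts were called, 1582 of them among the 1834. Thinning tests depth only, so other differences between libraries that go with age cannot be told apart from age. Skin replicate 1, a PN2 library of 11704985 counts, held 17.8 CPM of ENSRNOT00000042459.4 and 49.0 CPM of ENSRNOT00000042553.3. The other skin libraries, all with larger totals, held 0 and at most 0.999 CPM. Hypothalamus PN2 replicate 1, with 5495252 counts, held 58.5 and 10.2 CPM, while replicate 2, with 5607810, held 0 of both. In the hypothalamus library of PN7 they stood at 145 and 23.0 CPM. Both transcripts were thus also present in PN2 libraries with low totals. Their rises therefore cannot be told apart from differences that go with low totals. Skin replicate 1 held 0 CPM of ENSRNOT00000020049.4, but 8.16 CPM of ENSRNOT00000086716.1. The count was 1073 without hippocampus PN7 replicate 2, 3099 with DESeq2, 4309 with limma voom and 2359 without the libraries numbered 4 and 5.

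In hypothalamus the single PN7 library has no replicate, so a test of it assumes that it varies as the other groups do. Under that assumption it differed from the 2 PN2 libraries in 568 transcripts, 320 higher and 248 lower; with only these 3 libraries 5 transcripts were called, with limma voom 140 and with DESeq2 1508. Without hypothalamus PN2 replicate 1 the count was 2829, and 942 without the libraries numbered 4 and 5. Of the transcripts that rose with age in hippocampus and had at least 10 reads in hypothalamus, 450 of 686 (65.6%) were also higher in the hypothalamus PN7 library, against 50.6% of all 16267 such transcripts. Of those that fell, 820 of 1084 (75.6%) were also lower, against 49.4%. The median log2 change of the first set was 0.91 in hippocampus and 0.27 in hypothalamus, and that of the second -1.14 and -0.34. Over all 16267 transcripts the log2 changes correlated at r = 0.0363 (Spearman 0.154), across transcripts, which are not independent replicates. Under the same assumption, a test of the interaction of age and region called 537 transcripts, 323 higher and 214 lower in hypothalamus relative to hippocampus, which describes that library and does not establish a regional difference in change with age. That count was 331 with the replicate block, 146 with only the groups compared, where the split turned to 50 higher and 96 lower, 119 with limma voom, 1452 with DESeq2, 349 without hippocampus PN2 replicate 1, 2495 without hypothalamus PN2 replicate 1 and 823 without the libraries numbered 4 and 5.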

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

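The tests of a shared batch and of totals for the libraries numbered 4 and 5, and both tests of read leakage, were chosen after the result they measure was seen; the tests on thinned deviations and on held-out hypothalamus libraries were added later, with bounds set before their values were known, but which of the 4 held-out values to set against its bound was decided after. The count of higher transcripts left after thinning was also taken later, once their total after thinning was known.

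Within groups of 4 or 5 libraries, 35 sets of values were examined for a library far from the rest, and 3 were found where chance gives about 1.75. Bone marrow replicate 4 held 3057 CPM of ENSRNOT00000012494.6, against 62.9 to 232 CPM in the other 3. Skin replicate 1 held 49.0 CPM of ENSRNOT00000042553.3, against 0 to 0.999 CPM in the other 4, and 194 CPM of ENSRNOT00000075775.2, against 114 to 135 CPM. A test of the interaction of age and region called 537 transcripts, and rests on 1 hypothalamus library at PN7.

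The libraries numbered 4 and 5 (bone marrow 4, hippocampus PN2 4, skin 4 and 5) deviated from their group means in the same way across tissues. Over the 5 cross-tissue pairs the mean correlation of deviations was 0.201, from 0.155 to 0.270, against 0.0589 over 27 pairs of libraries numbered 1 to 3, so a shared batch of libraries is a candidate explanation; the labels name none. A few strongly deviating transcripts did not carry the pattern, since the mean was 0.140 without the 5% of transcripts that deviate most. Totals were above the others of their group in 3 of the 4 libraries, but with every library thinned to the smallest total the mean correlation was 0.232, from 0.185 to 0.292, which argues against depth. A difference between the pools of animals was not tested and stays open.

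Bone-marrow-restricted transcripts were present in the hypothalamus libraries of PN2 at 11.5% of the bone marrow level. An admixture of cells with the make-up of the whole bone marrow sort would keep the transcripts in their bone marrow ratios, but 26.5% of the 83 lay within 3-fold of the median ratio, against 77.1% when bone marrow replicate 4 was set against the other bone marrow libraries. In hippocampus the share was 44.6% at PN2 and 38.6% at PN7. The bone marrow libraries were deeper and held far higher levels of these transcripts, and the 2 hypothalamus libraries correlated at 0.821. Spread between libraries thus also lowers the 26.5%, and by how much was not tested. Leakage of reads met the bound first written for it, summed reads per library of 0.945 times those in hippocampus PN2. In a second test, chosen once that value was known, 51.8% of the transcripts had fewer than 1 in 10 of the reads that leakage in bone marrow proportions would need, and 21 had 0 reads, which argues against leakage as the source of the summed level. A cell type that makes up part of the bone marrow sort, or expression by hypothalamic mast cells themselves, may account for the pattern and was not tested.

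Transcripts higher in hypothalamus than in hippocampus at PN2 were weighed against 3 explanations. Lower depth in hypothalamus did not account for them, since of the 511 transcripts 435 to 452 were still called higher in 5 thinnings of every library to the smallest total, and 0 were called lower. In 93.9% both hypothalamus libraries lay above all 4 hippocampus libraries, which decides nothing as the same libraries made the calls; of transcripts called higher from 1 library alone, 56.5% to 68.9% lay higher in the held-out one, against 31.5% to 46.1% of all transcripts. Only the lowest of the 4 values meets the bound for dependence on 1 library (under 60%) and none the bound against it (at least 80%), so part of the calls may rest on 1 library and this stays open. With the hippocampus libraries divided between both tests, 228 transcripts were called higher in hypothalamus, of which 112 (49.1%) were also higher in bone marrow and 22 lower, against 8.16% of all transcripts higher there, which lies between the bounds set for (at least 50%) and against (under 25%) cells like those of the bone marrow sort, so these cannot be told apart from a difference between the regions.

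Other groupings of the same libraries were tested for the 4 comparisons with at least 3 libraries a side. In each, the real grouping gave the most calls. The smallest share that 35 splits allow is 0.0286. The other splits mix unlike groups, which adds spread and lowers their counts, so the real split had an advantage from the start. A batch of libraries that goes with the groups is not tested in this way. For hippocampus against bone marrow at PN2, 1 of 35 splits, the real one, called 5897 transcripts, and the highest other called 1. For hippocampus PN7 against PN2, 1 of 35 splits reached 1834, and the highest other, 209, set hippocampus PN2 replicates 1 to 3 against the rest. For hippocampus against skin at PN2, 1 of 100 splits drawn reached 1797, and the highest other, 370, set skin replicates 2 to 5 against the rest. For skin against bone marrow at PN2, 1 of 100 splits drawn reached 6981, and the highest other, 2859, differed from the real one in the place of skin replicate 3.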

How the results depend on the processing

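Over 31 other settings, those with identical transcripts merged, without or with a term for the libraries numbered 4 and 5, thinned, or with other class limits were chosen after seeing the data. Of the counts of differing transcripts, 127 lay within 1.5 times the reported count and 35 did not; of the values of named transcripts, 349 kept direction and call, 25 kept only the direction and 0 reversed. With limma voom the counts were 9533 (hippocampus against bone marrow), 4653 (hippocampus against skin), 4309 (hippocampus PN7 against PN2), 2278 (hypothalamus against bone marrow), 271 (hypothalamus against hippocampus), 598 (hypothalamus against skin), 140 (hypothalamus PN7 against PN2) and 119 (interaction). With DESeq2 they were 2819 (hippocampus against skin), 3099 (hippocampus PN7 against PN2), 2365 (hypothalamus against hippocampus), 1508 (hypothalamus PN7 against PN2) and 1452 (interaction). With only the groups compared they were 2796 (hippocampus against skin), 1962, 233 and 1451 (hypothalamus against bone marrow, hippocampus and skin), 5 (hypothalamus PN7 against PN2) and 146 (interaction). A term for the libraries numbered 4 and 5 gave 2129 for hypothalamus against hippocampus; leaving them out gave 2124 there, 942 for hypothalamus PN7 against PN2 and 823 for the interaction. Apart from the smaller set of libraries, the cause was not tested. Leaving out each replicate in turn gave 4956 to 5545 (hippocampus against bone marrow), 1183 to 1710 (hippocampus against skin), 6039 to 6770 (skin against bone marrow), 1073 to 1539 (hippocampus PN7 against PN2), 4466 to 6129, 796 to 3399 and 2178 to 4076 (hypothalamus against bone marrow, hippocampus and skin), 676 to 2829 (hypothalamus PN7 against PN2) and 349 to 2495 (interaction). A lone hypothalamus library left by this is assumed to vary like the other groups, and the highest hypothalamus values came from such fits; without the PN7 hypothalamus library no value could be had. The replicate numbers gave no firm sign of pairing. In no pair of groups with at least 3 shared numbers did every correlation of deviations exceed 0.1. Of 18 libraries, 8 correlated best with their own number, and no chance value was computed for this. Between bone marrow and hippocampus at PN2 all same-number correlations were positive (0.00674 to 0.270). The same held for bone marrow and skin (0.0292 to 0.164) and for hippocampus PN2 and skin (0.0187 to 0.208). Cross-tissue pairs of these groups averaged 0.0589 among libraries numbered 1 to 3, whether or not the numbers matched. Among those numbered 4 and 5 they averaged 0.201. Positive values alone are therefore no sign of pairing, and a partial pairing stays open. The replicate block gave 331 for the interaction and moved no other total by over 1.5 times; the transcripts higher in hypothalamus at PN7 than at PN2 numbered 191 with it, against 320. With RLE factors no total moved by over 1.5 times. The gene list tests and their alternatives were not run, since no transcript could be matched to a gene, and alternatives for normalized values did not apply. The smallest library held 5495252 counts, and with every library thinned to that total no count of differing transcripts moved by over 1.5 times.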

Other observations

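The bone-marrow-restricted signal in hypothalamus at PN2 was concentrated in few transcripts. Of its reads in the 2 libraries, 27.6% belonged to 1 transcript and 82.1% to 5 of the 83. Single transcripts reached a median of 1.05% of their bone marrow level in hypothalamus at PN2, and 17 of 83 exceeded 10% of it. In hippocampus at PN2 the median was 0.348% and 5 exceeded 10%.

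Of the 457 transcripts higher in hippocampus at PN2 than in both bone marrow and skin, 110 averaged at least 100 CPM in hippocampus. Against hippocampus at PN2, 62 of the 457 were lower and 11 higher in hypothalamus, and 47 were lower and 18 higher in hippocampus at PN7. Of the 187 lower than in both tissues, 35 were higher and 6 lower in hypothalamus, and 41 were higher and 4 lower at PN7. These comparisons share the hippocampus PN2 libraries that picked the transcripts, so part of the imbalance towards the other tissues' levels comes from that choice and its size was not estimated.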
